A study of Mus musculus with 6 samples.

How the data were processed

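PRO-seq reads of mouse PDAC cells were examined in 6 libraries, 2 from cells with R172H p53, 2 from an isogenic Trp53 knockout (KO) and 2 from the knockout with ectopic R172H p53 (add-back). Per the submitters' processing notes, adapters were trimmed with cutadapt and reads were aligned to mm10 with Bowtie2; versions and any removal of duplicates are not given in the sources used here. Each deposited file lists 1 aligned read per line with chromosome, start, end, read name, score and strand, and the score the authors wrote in each line is the mapping quality of the aligner. The files hold no counts. Scores ran from 22 to 44 in the R172H and KO files and from 0 to 42 in the add-back files. Read names differed as well. Those of R172H are the sequencer's own. Those of KO carry a serial number and a multiplicity, as a program that merges identical reads before alignment writes them, and 8.2% and 11.0% had a multiplicity above 1. All add-back names (100%) carry a random tag.

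The groups were taken from the sample labels, and the comparisons, their alternatives and the gene lists were chosen before the data were examined. Positions refer to mm10 with the GRCm38 gene table of 49997 genes, which gives no strand, so the strand of each gene was inferred from its reads. A strand was assigned when a gene had at least 10 reads and at least 75% of them on one strand. This gave 16202 of 22045 genes with reads, and 24 of 25 genes of known strand were assigned, 24 of them to the known strand. Of 5242 long genes, 4360 (83.2%) had more reads at the inferred start than at the end.

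Each read was counted at its end next to the polymerase. Gene bodies ran from 500 nt downstream of the start to the end and were at least 500 nt long, and promoter-proximal windows covered the first 250 nt. Of the genes, 4975 overlapped another gene on the same strand, and reads running in from upstream were gauged by the pooled sense density 500 to 2500 nt upstream of the start over that of the body. Genes with a depth-scaled minimum of 10 reads in a group's number of libraries and 15 in total were tested, which left 14461 genes, 11122 of them protein-coding. Library sizes were scaled by the trimmed mean of M values (TMM; trims of 30% and 5%), in a separate implementation, with factors of 0.9258, 0.9565, 0.9957, 1.015, 1.057 and 1.058 for the 2 libraries each of R172H, KO and add-back. A count-based test had been planned for read counts, with limma in its place only where no counts could be had. Counts were made here from the reads, so the use of limma-voom departed from that plan. Gene-body counts were fitted with limma-voom (limma 3.58.1 in R 4.3.3, offset 0.5), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

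Distal elements were windows of 1000 nt with at least 20 pooled reads on each side of a divergent centre within 250 nt and more than 5 kb from any gene. They were tested by limma-voom with the gene-body scaling. Pausing ratios were log2 ratios of promoter-proximal to body density with a pseudocount of 1 in genes with at least 20 pooled promoter-proximal and 20 pooled body reads, tested by limma. Lists of genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation; fry, which tests a list against no change, was run as an alternative. The 23 lists were CXC chemokines, CC chemokines and colony-stimulating factors, NF-kB targets, p53 targets, sterol synthesis, interferon-stimulated genes, antigen presentation, epithelial identity, mesenchymal genes, classical PDAC and foregut genes, basal and squamous genes, G2 and M phase genes, DNA replication, immediate-early genes, RAS-ERK output, TGF-beta and YAP targets, hypoxia and glycolysis, stress response, ribosomal proteins, and markers of immune cells, fibroblasts, endothelium, and acinar and islet cells.

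Genes were named by a rule. For each comparison with KO the 8 largest rises and 8 largest falls were taken, and 5 of each for add-back against R172H. They came from protein-coding genes past an adjusted p of 0.05 with a mean of at least 20 normalized body reads per library in the higher group and no overlap between replicates. Up to 3 members of each list with the smallest p in R172H against KO were added, together with Trp53, Cxcl1, Cxcl2, Cxcl3 and Cxcl5. The 5 largest rises and falls were named for elements and pausing, with the elements within 500 kb of Cxcl1. In 732 genes with bodies of at least 2000 nt, one or more windows of 100 nt held over 20% of the pooled body reads. Lower bounds were set at 3 reads over a group.

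The tests were tried on simulated data with the depth of these libraries, with the R172H group changed. Of 200 changed genes, 53.6% were recovered at a log2 change of 1 and 93.3% at 2, with 3 of 13905 unchanged genes called. For elements, 76% of 100 changed ones were recovered at a log2 change of 2, with 1 unchanged one called. For pausing, 25% were recovered at a difference of 2 and 90.6% at 4, with 5 unchanged genes called. An offset from neighbouring genes took a simulated shift of a whole chromosome from 0.49 to 0. Alternatives covered scaling, windows, thresholds, score (at least 30), leaving out each library, an offset from 50 neighbouring genes and the replicate number as a block. Further ones were added after the results were seen, namely median-of-ratios scaling, limma-trend, centred pausing ratios, removal of piled windows, estimated correlations in camera under other settings, each comparison against a different KO library, and matched reads, which were 30 to 50 nt long with a score of at least 30 and each position counted once.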

Results

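Nascent transcription was measured by precision run-on sequencing (PRO-seq), in which engaged RNA polymerases add a biotin-labelled nucleotide in isolated nuclei. The labelled RNA is purified and sequenced, so that read density follows engaged polymerase rather than steady-state mRNA. The cells were mouse pancreatic ductal adenocarcinoma (PDAC) cells in 3 groups of 2 libraries. One group carried the R172H form of p53 (R172H). The second was an isogenic line whose Trp53 gene was knocked out with CRISPR-Cas9 (KO). The third was the knockout with ectopically expressed R172H p53 (add-back). The libraries held 6158167 and 5943038 aligned reads for R172H, 9273266 and 13495698 for KO and 9203939 and 8521449 for add-back. Of these, 3118910, 3041245, 5587374, 8654770, 5898928 and 5394082 fell in gene bodies. The libraries also differed by group in ways other than genotype. Median read length was 25 and 24 nt in R172H, 52 and 60 nt in KO and 37 and 38 nt in add-back, and the share of reads at a distinct position was 74.9% and 75.9%, 83.4% and 86.4%, and 96.9% and 96.4%. A window of ribosomal DNA held 9.85% and 9.61% of the nuclear reads in R172H, 9.06% and 6.04% in KO and 0.09% in both add-back libraries. Because each group had its own kind of library, preparation and genotype cannot be told apart. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples. Correlations of log2 gene-body values over genes were 0.978 to 0.988 within groups and 0.849 to 0.913 between them. Levels below are gene-body reads-per-million (RPM; mean ± SD, n = 2), scaled to each library's TMM-adjusted gene-body total, and positions are on mm10 (GRCm38).

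The knockout was first examined at its target. Trp53 encodes the p53 transcription factor and lies on chromosome 11 at 69580348 to 69591873. Its gene-body level was 50.8 ± 0.231 in R172H, 30.8 ± 1.77 in KO and 55.8 ± 6.69 in add-back. By limma-voom with Benjamini-Hochberg adjustment, Trp53 was higher in R172H than in KO (log2 fold change 0.74, SE 0.14, adjusted p = 0.0002) and higher in add-back than in KO (0.86, SE 0.11, adjusted p = 7.53e-06), and the sum over the body did not differ detectably between add-back and R172H (0.12, SE 0.13, adjusted p = 0.439), although their profiles along Trp53 were unlike. The difference was concentrated in an 8.0 kb stretch of the gene, from 69583001 to 69591000, that was delimited after the KO profile was seen. Sense RPM there were 29.2 and 26.9 in the R172H libraries, 0 and 0.46 in the KO libraries (4 reads in all) and 31.8 and 36.5 in the add-back libraries. From 69583501 to 69586500 both add-back libraries had 0 sense reads, whereas both R172H libraries had reads in each 500-nt window. The add-back reads lay further downstream, with 85 and 96 of them between 69588501 and 69589000, against 7 and 5 in R172H. Transcription through the locus would also leave reads from 69583501 to 69586500. The 0 counts there argue against it as the source of the add-back reads within this stretch. Whether the add-back reads came from the ectopic Trp53 sequence was not tested. Between the body start and this stretch, sense RPM were 27.9 ± 1.82 in KO, against 17.6 ± 3.34 in R172H and 18.4 ± 2.58 in add-back.

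**Figure D1:**
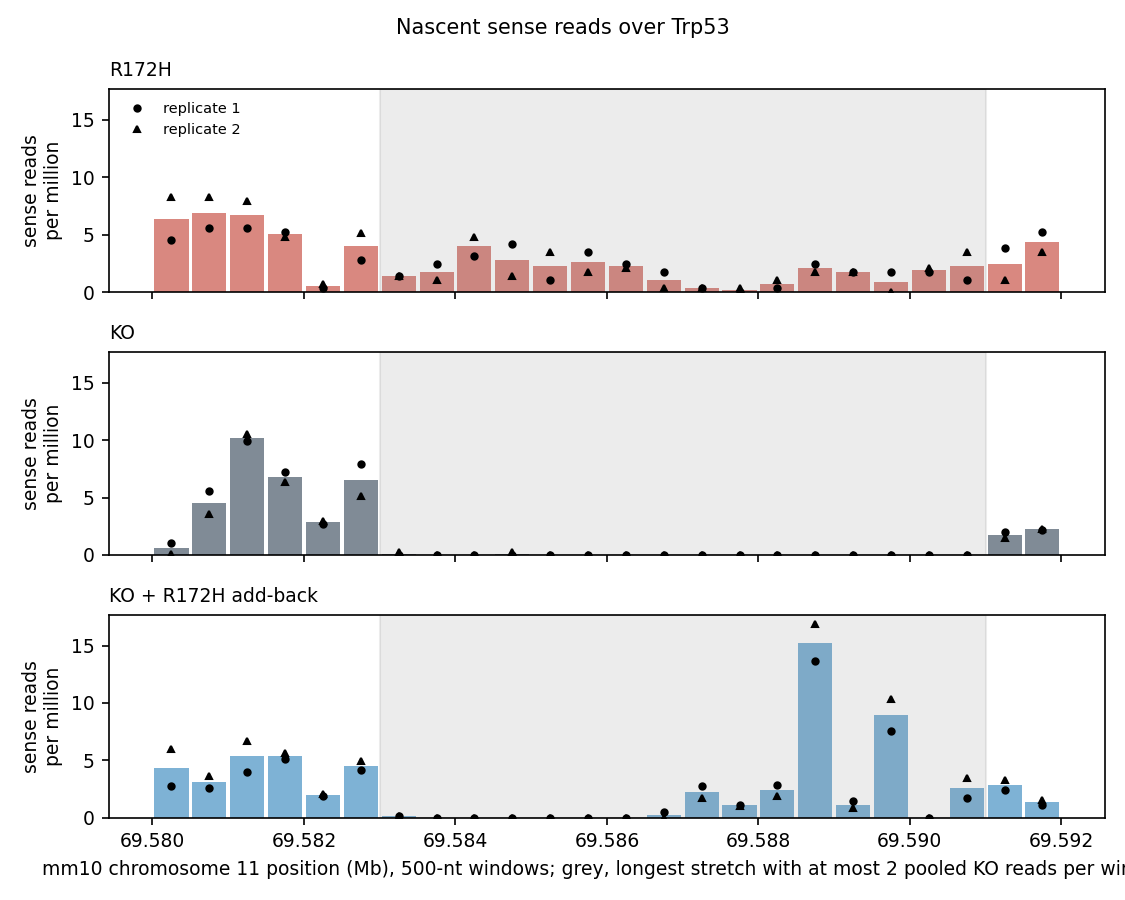
Sense RPM in 500-nt windows along Trp53 (x axis, mm10 position on chromosome 11 in Mb) for the libraries of R172H, KO and add-back cells; grey marks the longest stretch with at most 2 pooled KO reads per window. R172H had 28.04 ± 1.61 RPM in that stretch, KO 0.23 ± 0.33 and add-back 34.1 ± 3.33.

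R172H was compared with KO to ask which transcription accompanies mutant p53 in PDAC cells. Several groups of genes were higher in R172H. Of 22 tested genes of mevalonate and sterol synthesis 21 rose (21 also when adjusted over the list alone), with a median log2 fold change of 1.21. They included Hmgcs1, which makes HMG-CoA (190 ± 17.1 against 61.7 ± 1.04, log2 1.62, SE 0.09), Insig1, a sterol-regulated inhibitor of SREBP processing (157 ± 11.6 against 56.0 ± 1.48, log2 1.49), and Cyp51, a demethylase of the cholesterol pathway (226 ± 18.2 against 99.96 ± 4.21, log2 1.17). Ggps1 fell by 0.71 (adjusted p = 0.0193); here and below, members named as the exceptions of a list were chosen after their values were seen. The list as a whole was shifted upward against other genes (camera, adjusted p = 1.27e-10; adjusted p = 0.27 with an estimated correlation). Of 35 genes of the G2 and M phases of the cell cycle 25 rose, 1 fell and 9 were not called (27 and 1 when adjusted over the list alone). The kinetochore genes Cenpe and Cenpf had log2 changes of 1.53 (SE 0.08) and 1.42 (SE 0.08), Ccna2, encoding cyclin A2, had 1.41, and Bub3 fell by 0.33 (adjusted p = 0.0351). The list median was 0.56 (camera adjusted p = 1.23e-06; adjusted p = 0.27 with an estimated correlation).

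Of 28 targets of TGF-beta and YAP, 17 rose, 5 fell and 6 were not called, and the same numbers were called when adjusted over the list alone (median 0.84, camera adjusted p = 0.000259; adjusted p = 0.27 with an estimated correlation). The matricellular genes Ccn2 (279 ± 18.6 against 46.1 ± 4.06, log2 2.61, SE 0.10), Ccn1 (267 ± 37.0 against 57.2 ± 0.494, log2 2.21) and Thbs1 (56.7 ± 2.16 against 7.52 ± 0.313, log2 2.91) rose. Skil, Amotl1, Lats2, Crim1 and Bhlhe40 fell. Epithelial genes rose in 18 cases and fell in 6 of 31 (18 and 6 when adjusted over the list alone; median 0.71, camera adjusted p = 0.00365; adjusted p = 0.676 with an estimated correlation). The keratins Krt7 and Krt19 rose to 672 ± 18.6 and 338 ± 3.67 from 281 ± 20.2 and 136 ± 1.04, and the tight-junction gene Marveld3 had a log2 change of 3.20, although 46.7% of its pooled body reads lay in one 100-nt window. Of 21 genes of the classical PDAC subtype and foregut, 15 rose and 4 fell (15 and 4 when adjusted over the list alone; median 0.66, camera adjusted p = 0.00387; adjusted p = 0.414 with an estimated correlation). Among them were Pdx1, a pancreatic transcription factor (108 ± 1.77 against 36.4 ± 1.08, log2 1.57), Tspan8 (log2 1.32) and Vsig1 (log2 2.52), while Hnf4g, Anxa10, Vsig2 and Spdef fell. The stress-response list moved downward, with 18 of 32 genes lower and 9 higher (18 and 10 when adjusted over the list alone; median −0.37, camera adjusted p = 0.0131; adjusted p = 0.676 with an estimated correlation). The genes lower in R172H included Cth, an enzyme of cysteine synthesis (6.57 ± 0.455 against 162 ± 6.94, log2 −4.58, SE 0.24), Trib3, a pseudokinase induced by amino acid stress (16.8 ± 2.28 against 160 ± 15.2, log2 −3.23) and Asns, asparagine synthetase (62.4 ± 2.52 against 195 ± 0.694, log2 −1.64). The endoplasmic reticulum chaperone genes Hsp90b1 (log2 0.93) and Sdf2l1 (log2 2.51) of the same list were higher, and were named after their values were seen.

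Over all genes, 4243 of 14461 tested were higher and 3811 lower in R172H than in KO by limma-voom at an adjusted p under 0.05, and 1890 and 1102 of these differed at least 2-fold. With library totals in place of the scaling factors 3664 were higher and 4615 lower, so which direction held more genes depended on the scaling. Folds against a group with 0 reads are lower bounds, set against 3 reads over that group, and intervals and floors cover counting error only, since PCR copies could not be told from separate molecules in all libraries. Nexmif, a neuronal X-linked gene at X:104076761 to 104201783, was at least 257.5-fold higher (53.9 ± 2.23 against 0 reads in KO), and Ccdc149 was at least 171-fold higher. Among the largest falls, Mmp13, a collagenase, went from 69.5 ± 0.152 in KO to 2.07 ± 0.478 in R172H (log2 −4.97, SE 0.38), Bdh1, a ketone-body enzyme, from 74.0 ± 9.65 to 2.59 ± 0.231 (log2 −4.72), Shfl, an antiviral gene, from 56.7 ± 8.33 to 2.07 ± 0.478 (log2 −4.64) and Havcr2, which encodes the receptor TIM-3, from 39.6 ± 1.22 to 0.690 ± 0.485 (log2 −5.64). Icam2, Dynap and Isx had 0 reads in R172H and were at least 16.2-, 12.4- and 11.3-fold lower, and Cdh9, with 2 reads in R172H, was 42-fold lower (95% counting interval 11.5 to 349). For Icam2 the sense density 500 to 2500 nt upstream of the start was 24.3 times that of the body, so its body reads could not be told from transcription running in from upstream. Of the genes named from the lists above, the density upstream exceeded that of the body in Spdef (3.12 times). The other 6 of the 8 largest rises, in Hfm1, Oma1, Adra2c, Rtn1, Adamts9 and Itga8, lay in piles of reads, with 96.3% to 99.9% of the pooled body reads in one 100-nt window. The call of Adra2c was lost without KO replicate 1 (log2 10.38, adjusted p = 0.0769) or KO replicate 2 (9.72, adjusted p = 0.107). Outside such piles and chosen after the values were seen, the transcription factor genes Prdm5 (71.7 ± 2.07 in R172H against 0.417 ± 0.428) and Sox11 were also far higher in R172H. With reads matched between libraries in length, score and duplicates, 5101 of 12453 genes were called, and the fall of the stress-response list was not (adjusted p = 0.0521). With an estimated correlation camera called 0 of 23 lists after adjustment and 3 at an unadjusted p under 0.05, against 6 at the preset correlation after adjustment.

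The series title names Cxcl1, which encodes a chemokine that attracts neutrophils, and its distal enhancers. Cxcl1 lies on chromosome 5 at 90891245 to 90893121 within a cluster of CXC chemokine genes. Its gene-body level was 18.3 ± 3.82 in R172H, 8.91 ± 1.91 in KO and 13.7 ± 1.52 in add-back. Cxcl1 was higher in R172H than in KO (log2 1, SE 0.23, adjusted p = 0.00137) and in add-back than in KO (log2 0.59, SE 0.21, adjusted p = 0.0221), and add-back against R172H was not called (log2 −0.41, adjusted p = 0.13), except with scores of at least 30 (−0.56, adjusted p = 0.0462). Over the whole gene, start included, plus-strand RPM were 66.9 ± 6.77, 13.8 ± 1.11 and 26.9 ± 0.86. This span adds promoter-proximal reads, which were raised across protein-coding genes in R172H. Per 100 body reads there were 15.8 and 13.6 in R172H, 4.2 and 2.6 in KO and 4.9 and 6.3 in add-back. The larger difference over the whole gene could not be told apart from that general rise. In the same cluster, Cxcl5, at 90759298 to 90761625, had 52.4 ± 0.999, 11.4 ± 2.11 and 80.4 ± 1.26 gene-body RPM (log2 2.17, adjusted p = 9.54e-09 in R172H over KO and log2 2.79, adjusted p = 7.05e-11 in add-back over KO). Cxcl3, at 90786101 to 90788093, had 4.66 ± 2.66, 1.25 ± 0.492 and 9.287 ± 2.003 (log2 1.73, adjusted p = 0.00908; log2 2.78, adjusted p = 3.59e-05). Cxcl2 was not tested, with 5, 3 and 2 plus-strand reads over the gene. Of the 6 tested CXC chemokines, 4 rose and 1 fell in R172H and 4 rose in add-back (the same when adjusted over the list alone), but the list was not shifted against other genes (camera adjusted p = 0.279 and 0.107; adjusted p = 0.866 and 0.865 with an estimated correlation). The fourth gene that rose was Ppbp, whose reads lay mostly on the strand opposite to those of its neighbours (17 minus-strand against 9 plus-strand reads in R172H), so their origin in Ppbp is not settled. The call of Cxcl1 in add-back over KO was lost without KO replicate 1 (log2 0.41, adjusted p = 0.134), without add-back replicate 1 (0.48, adjusted p = 0.16), with matched reads (0.44, adjusted p = 0.268) and with an offset from neighbouring genes (0.50, adjusted p = 0.0541). The call of Cxcl3 in R172H over KO was lost without R172H replicate 2 (1.16, adjusted p = 0.12) and with a body starting 1000 nt downstream (1.54, adjusted p = 0.0566).

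**Figure D2:**
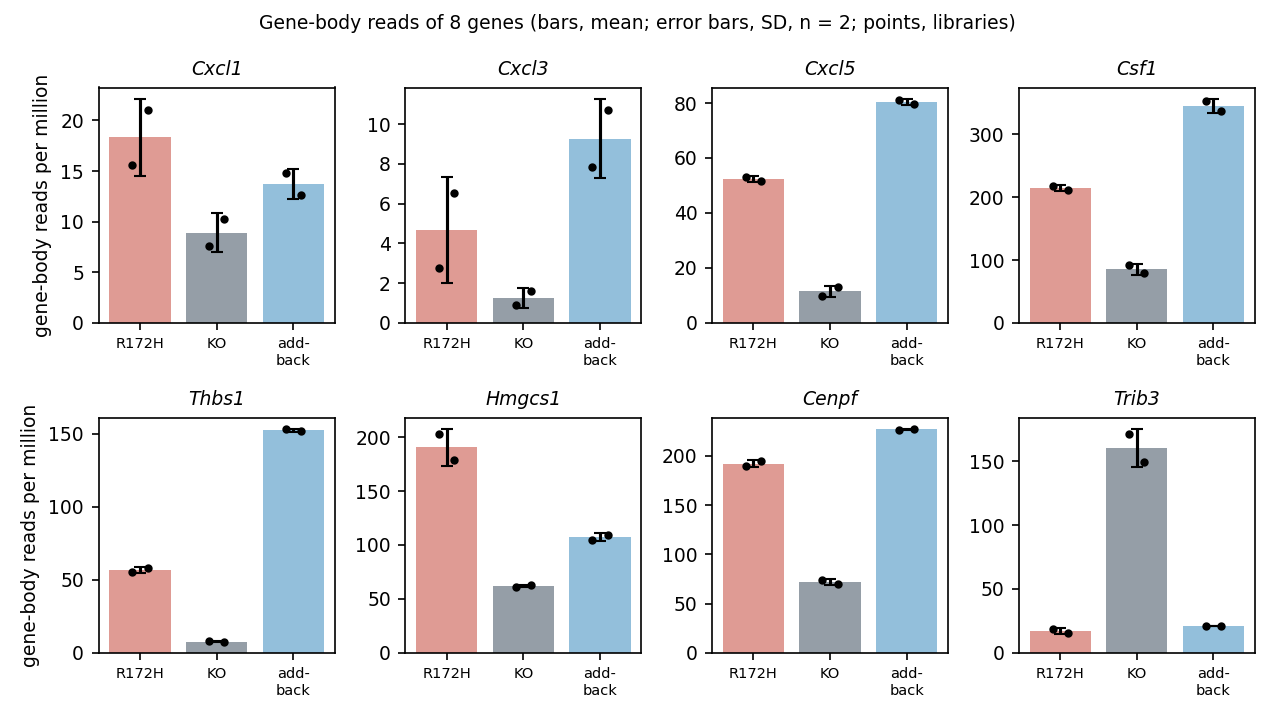
Gene-body RPM (y axis) of 8 genes in R172H, KO and add-back cells; bars are means, error bars SD (n = 2) and points libraries, and the genes were chosen after their values were seen. Cxcl1 stood at 18.3, 8.91 and 13.7, Thbs1 at 56.7, 7.52 and 152.7, and Trib3 at 16.8, 160 and 20.9 RPM.

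Distal elements were defined, without regard to group, as sites of divergent transcription more than 5 kb from any gene, as active enhancers often show. Of 758 elements, 553 were higher and 30 lower in R172H than in KO (median log2 1.47), and 424 were higher and 42 lower in add-back than in KO (median log2 0.90), by limma-voom with the gene-body scaling. Of these, 2 lay within 500 kb of Cxcl1. The first, at 5:90689475 to 90690474, at −201.3 kb from the Cxcl1 start, had 6.40 ± 0.766, 1.82 ± 0.479 and 4.03 ± 0.252 RPM in R172H, KO and add-back (log2 1.88, SE 0.42, adjusted p = 0.000487 in R172H over KO; log2 1.21, SE 0.40, adjusted p = 0.0143 in add-back over KO). The second, at 5:90875725 to 90876724, at −15 kb, had 5.18 ± 0.951, 2.02 ± 0.0513 and 4.46 ± 0.397 (log2 1.34, SE 0.42, adjusted p = 0.00687; log2 1.11, SE 0.38, adjusted p = 0.0168). Adjusted over these elements alone the values in R172H over KO were 0.000433 and 0.00451. The log2 changes of the 2 elements in R172H over KO lay on either side of the median of all elements, 1.47. In add-back over KO both were above the median of 0.90. Elsewhere, an element at 2:129330350 to 129331349, 31.2 kb from the cytokine gene Il1a, had a log2 change of 4.40 in R172H and 3.34 in add-back over KO, and one at 6:139586575 to 139587574, 27 kb from Pik3c2g, had 6.44 in R172H with 0 and 1 reads in the KO libraries. An element at 2:157412150 to 157413149, 11.3 kb from the kinase gene Src, fell by 1.90 in R172H and by 2.18 in add-back. Reads in elements were 0.99% and 0.96% of body reads in R172H, 0.65% and 0.72% in add-back and 0.51% and 0.42% in KO. The groups stood in the same order for promoter-proximal reads per 100 body reads. The excess of higher elements could not be told apart from that general difference, and it depended on the scaling. With factors estimated from the elements themselves, 146 were higher and 180 lower in R172H (median log2 0.01) and 148 higher and 182 lower in add-back (median 0.02). With matched reads the medians were 0.88 and 0.52. With the factors from the elements, neither element near Cxcl1 was called in R172H over KO (log2 0.39, adjusted p = 0.489; log2 −0.12, adjusted p = 0.863). The nearer one also lost its call without R172H replicate 2 (1.18, adjusted p = 0.0804) and with matched reads (−1, adjusted p = 0.452). In add-back over KO both lost theirs with factors from the elements (0.30, adjusted p = 0.593; 0.24, adjusted p = 0.659), with matched reads (1.59, adjusted p = 0.0622; 0.66, adjusted p = 0.352), without KO replicate 2 (0.86, adjusted p = 0.165; 1.12, adjusted p = 0.0748) and without add-back replicate 2 (1.17, adjusted p = 0.0689; 1.03, adjusted p = 0.0868).

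Add-back was compared with KO to ask what follows the return of mutant p53 to cells without it. Of 35 G2 and M phase genes 31 rose (31 when adjusted over the list alone), with a median log2 change of 0.59 (camera adjusted p = 3.63e-10; adjusted p = 0.335 with an estimated correlation). Cenpf rose to 227 ± 0.545 from 71.9 ± 2.88 in KO (log2 1.66, SE 0.07) and Cenpe to 209 ± 1.70 from 88.6 ± 5.23 (log2 1.23). Sterol genes rose in 18 and fell in 1 of 22 cases (18 and 1 when adjusted over the list alone; median 0.62, camera adjusted p = 5.26e-05; adjusted p = 0.344 with an estimated correlation), with Hmgcs1 at log2 0.79 (SE 0.09), Insig1 at 0.57 and Cyp51 at 0.49; Msmo1 fell by 0.57. Ribosomal protein genes fell in 43 of 46 cases (45 when adjusted over the list alone), with a median of −0.59 (camera adjusted p = 1.48e-11; adjusted p = 0.344 with an estimated correlation). Rps24 dropped from 114 ± 2.69 to 39.7 ± 0.250 (log2 −1.53, SE 0.10), and Rpl19 and Rpl30 fell by 0.37 and 0.36. The last 2 calls were lost without add-back replicate 1 (−0.31, adjusted p = 0.0854; −0.26, adjusted p = 0.134), and that of Rpl30 without KO replicate 2 (−0.32, adjusted p = 0.0529), with matched reads (−0.26, adjusted p = 0.27) and with reads at one position counted once (−0.24, adjusted p = 0.0572). Of 32 stress-response genes 21 fell and 5 rose (22 and 6 when adjusted over the list alone; median −0.79, camera adjusted p = 7.44e-06; adjusted p = 0.344 with an estimated correlation), with log2 changes of −3.52 for Cth, −2.91 for Trib3 and −1.80 for Asns. Basal and squamous genes fell in 8 of 11 cases (8 when adjusted over the list alone; median −0.67, camera adjusted p = 0.000791; adjusted p = 0.335 with an estimated correlation). These included the EGF receptor ligands Areg (51.9 ± 1.15 against 286 ± 8.22, log2 −2.46, SE 0.08), Ereg (log2 −1.66) and Hbegf, whose fall of −0.26 became 0.17 (adjusted p = 0.115) with an offset from neighbouring genes. The call of Hbegf was also lost without KO replicate 2 (−0.20, adjusted p = 0.07), add-back replicate 1 (−0.25, adjusted p = 0.0596) or add-back replicate 2 (−0.25, adjusted p = 0.0504).

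With an estimated correlation camera called 0 of 23 lists in add-back against KO (2 at an unadjusted p under 0.05), and 5 at the preset correlation. In add-back against KO, 4093 of 14461 genes were higher and 4102 lower, of which 1316 and 1036 differed at least 2-fold. With library totals 4636 were higher and 3505 lower. Thbs1, a thrombospondin, rose to 153 ± 1.02 from 7.52 ± 0.313 (log2 4.34, SE 0.15, adjusted p = 8.46e-13), and Csf1, the macrophage growth factor, to 346 ± 11.2 from 85.3 ± 9.11 (log2 2.04, SE 0.07). Among the largest rises, Klhdc7a stood at 30.4 ± 2.14 against 0.294 ± 0.0933 (log2 6.46), Hoxa3 at 26.0 ± 1.34 against 0.522 ± 0.229 (log2 5.44), and Cyp2j6 and Snca, the alpha-synuclein gene, were at least 37.65- and 28.04-fold higher than in KO, where they had 0 reads. Mndal, an interferon-inducible gene with 2 KO reads, was 49.3-fold higher (95% counting interval 13.2 to 414), and Gm4951 and Gm4907, with 1 KO read each, were 119- and 97.3-fold higher (intervals 20.9 to 4746 and 16.98 to 3892). Saxo1, at least 36.45-fold higher, had 88.8% of its pooled reads in one 100-nt window. The density upstream was 3.15 times that of the body in Gm4907, 2.31 times in Saxo1 and 1.01 times in Elfn2. Among the largest falls, Tenm2, a teneurin gene at 11:36006656 to 37237053, went from 342 ± 9.69 to 1.07 ± 0.526 (log2 −8.26, SE 0.41), and Atp13a4, Tspan12 and Elfn2 had 0 reads in add-back and were at least 97.9-, 35.5- and 26.35-fold lower. The reads counted for Tenm2 lay on the plus strand, which was inferred from the reads alone, so their origin in Tenm2 is not settled. The other 4 of the 8 largest falls, Timd2, Stap2, Taco1 and Il1rapl1, had 78.2% to 99.9% of their reads in one window; without these windows the log2 change of Stap2 was 0.03, of Taco1 0.61 and of Il1rapl1 2.14, and with scores of at least 30 that of Timd2 was −1.31 (adjusted p = 0.39). Wnt7a, chosen after its value was seen, fell by 5.88 outside such windows.

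A gene was called in both comparisons with the same sign in 4287 cases, 2119 higher and 2168 lower than in KO, and with opposite signs in 957. Genes higher in both included 23 of the G2 and M phase list, among them Cenpe, Cenpf and Ccna2, 18 of the sterol list, among them Hmgcs1, Insig1 and Cyp51, and the chemokine genes Cxcl1, Cxcl3 and Cxcl5. Genes lower in both included 17 of the stress-response list, among them Cth, Trib3 and Asns. Both comparisons used the same KO libraries. Independent lists of these sizes would share 1201 higher and 1081 lower genes. The correlation of log2 fold changes over genes, which are not independent replicates, was 0.43. In 20 simulations of unchanged groups, all 6 libraries were drawn anew at the KO rates. Both comparisons again shared their KO libraries. The correlation averaged 0.44 there, so it did not separate shared changes from shared controls. The covariance of the log2 fold changes was 0.539 against a simulated 0.0374. The highest count called alike in any simulation was 0, but the simulations held no differences in line or preparation. In a split chosen after these counts were seen, each comparison used a different KO library. With R172H over KO replicate 1 and add-back over KO replicate 2, 3605 of 14279 genes were called alike and 689 with opposite signs (1732 higher and 1873 lower, against 886 and 875 for independent lists; correlation 0.40, covariance 0.478). With the KO libraries exchanged these were 3320 and 956 (1569 and 1751, against 906 and 914; 0.32 and 0.398). A lone KO library was assumed to vary like the other groups. Changes particular to the KO line, or to the preparation of the KO libraries, remain shared in any split.

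**Figure D3:**
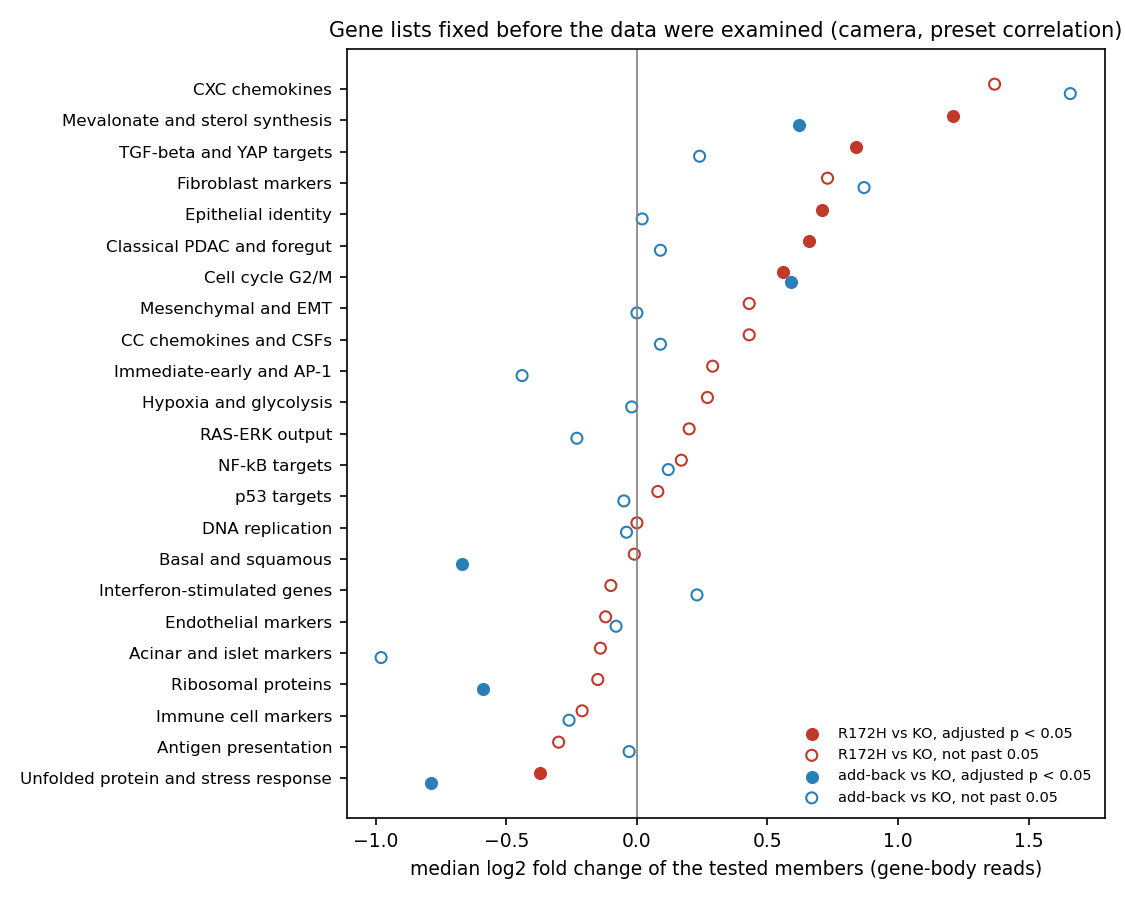
Median log2 fold change (x axis) of the tested members of each of 23 gene lists in R172H over KO and in add-back over KO; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation, and at an estimated correlation 0 of the 23 were called in either comparison. Sterol synthesis had medians of 1.21 and 0.62, G2 and M phase genes 0.56 and 0.59, and stress-response genes −0.37 and −0.79.

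Add-back was compared with R172H to ask how far the ectopic protein restored the parental state. Several lists were lower in add-back. Sterol genes fell in 18 and rose in 1 of 22 cases (18 and 1 when adjusted over the list alone; median −0.65, camera adjusted p = 2.97e-06; adjusted p = 0.22 with an estimated correlation), with Hmgcs1 at log2 −0.83 (SE 0.08); Ggps1 rose. Classical PDAC genes fell in 15 and rose in 1 of 21 (15 and 1 when adjusted over the list alone; camera adjusted p = 5.89e-05; adjusted p = 0.22 with an estimated correlation), with Vsig1 at −1.51 and Pdx1 at −0.69; Hnf4g rose. Basal genes fell in 10 of 11 (10 when adjusted over the list alone; camera adjusted p = 5.89e-05; adjusted p = 0.22 with an estimated correlation), with Areg at −1.40. Epithelial genes fell in 19 and rose in 5 of 31 (19 and 5 when adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.506 with an estimated correlation), with Krt7 at 240 ± 3.84 against 672 ± 18.6 (log2 −1.48, SE 0.06); Grhl3, Sox9, Pkp3, Jup and Lsr rose (upstream densities of 2.37 times the body in Pkp3 and 1.61 times in Lsr). RAS-ERK output genes fell in 17 and rose in 3 of 23 (17 and 3 when adjusted over the list alone; camera adjusted p = 5.89e-05; adjusted p = 0.22 with an estimated correlation), with the ERK phosphatase gene Dusp4 at −0.70. Dusp4 lies on chromosome 8, whose gene median was −0.61, and with an offset from neighbouring genes it was no longer called (−0.14, adjusted p = 0.291). Immediate-early genes fell in 16 and rose in 2 of 26 (18 and 2 when adjusted over the list alone; camera adjusted p = 0.000744; adjusted p = 0.631 with an estimated correlation), with Myc at −1.21, and Atf3 and Btg2 rose. Ribosomal protein genes fell in 29 and rose in 2 of 46 (29 and 2 when adjusted over the list alone; camera adjusted p = 8.37e-06; adjusted p = 0.49 with an estimated correlation), and hypoxia and glycolysis genes fell in 17 and rose in 2 of 28 (17 and 2 when adjusted over the list alone; camera adjusted p = 0.00471; adjusted p = 0.22 with an estimated correlation). Other lists that had moved against KO were not called here. G2 and M phase genes were 7 higher and 6 lower of 35 (7 and 5 when adjusted over the list alone; median 0.08, camera adjusted p = 0.506; 0.797 with an estimated correlation), and TGF-beta and YAP targets 7 higher and 15 lower of 28 (7 and 15; median −0.29, 0.0754; 0.49). Stress-response genes were 7 higher and 13 lower of 32 (8 and 13; median −0.19, 0.18; 0.727). CXC chemokines, not called against KO either, were 3 higher of 6 (3; median 0.36, 0.543; 0.812).

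With an estimated correlation camera called 0 of 23 lists here (5 at an unadjusted p under 0.05) and 8 at the preset correlation. Over all genes, 3370 were higher and 3814 lower in add-back than in R172H, 46.9% of the calls being higher. With library totals in place of the scaling factors the median of all genes lay at 0.16 and 4763 genes were called higher and 2882 lower (62.3% higher), so these counts are relative to the scaling used. Isx, an intestinal homeobox gene at 8:74873174 to 74893506, was at least 136-fold higher in add-back (70.4 ± 1.06 against 0 reads), Hoxc4 had 48.8 ± 3.24 against 0.691 ± 0.00351 (log2 5.82), and Gm4907 and Lingo4 were at least 13.1- and 12.8-fold higher. Hoxc4, which overlaps another gene on its strand, Gm4907 and Lingo4 had upstream densities of 1.89, 3.15 and 1.63 times that of the body, so the origin of their reads is not settled. Cdh9, a cadherin gene, stood at 107 ± 20.4 against 2 reads in R172H, a ratio of 311 (95% counting interval 86.0 to 2572). Prdm5 was at least 285-fold lower in add-back. The other 4 of the 5 largest falls, in Rtn1, Timd2, Adra2c and Hfm1, had 98.7% to 99.9% of their pooled reads in one 100-nt window, and the call of Adra2c was lost without add-back replicate 1 (−9.75, adjusted p = 0.0844) or 2 (−9.88, adjusted p = 0.083). Cxcl5 and Cxcl3 were higher in add-back than in R172H (log2 0.62, adjusted p = 0.000305; log2 1.05, adjusted p = 0.0306), but the log2 change of Cxcl3 was −0.11 with matched reads (adjusted p = 0.88) and 0.44 without R172H replicate 1 (adjusted p = 0.407). Its call was also lost without add-back replicate 2 (0.84, adjusted p = 0.134).

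Changes also ran along whole chromosomes. In add-back against R172H the median log2 change of the genes of chromosome 8 was −0.61, of chromosome 12 −0.54, of chromosome 1 0.39 and of chromosome 17 0.31. In add-back against KO chromosome 14 had −0.54, chromosome 8 −0.40 and chromosome 1 0.36, and in R172H against KO chromosome 9 had −0.33 and chromosomes 12 and 18 0.30. On chromosome 5, which holds the Cxcl cluster, the medians were 0.09, 0.01 and −0.10 in R172H over KO, add-back over KO and add-back over R172H. Its share of the reads more than 20 kb from genes, however, had log2 changes of 0.81, 0.55 and −0.26, the first and second being the largest rises of any chromosome, so the elements near Cxcl1 lie on a chromosome with raised intergenic reads. With an offset from the 50 neighbouring genes the calls also made were 82.8%, 73.4% and 69.4% in these comparisons.

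**Figure D4:**
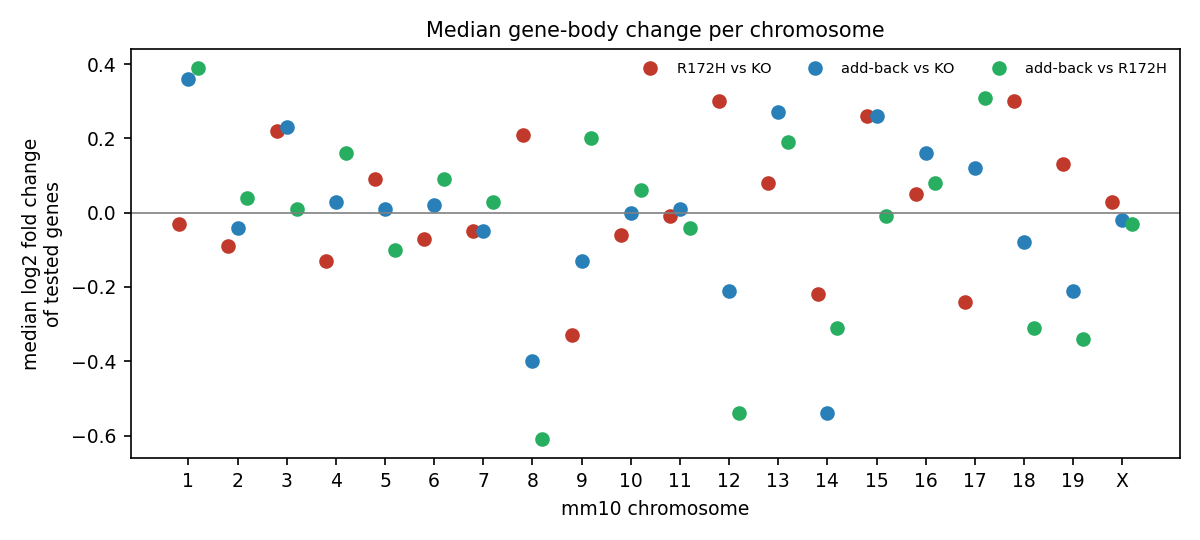
Median log2 fold change of the tested genes (y axis) on each mm10 chromosome (x axis) in the 3 comparisons. In add-back over R172H, chromosome 8 lay at −0.61 over 794 genes and chromosome 1 at 0.39 over 893 genes.

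The distribution of polymerases along genes was compared through the log2 ratio of promoter-proximal to gene-body density in 9504 genes, which is high where polymerases pause downstream of the start. The median ratio was 4.33 and 4.11 in R172H, 2.28 and 1.63 in KO and 2.83 and 3.17 in add-back. Across groups it was lower where reads were longer. Median lengths were 25 and 24 nt in R172H, 37 and 38 nt in add-back and 52 and 60 nt in KO. The KO library with the longer reads also had the lower ratio. A difference in pausing could therefore not be told apart from one in read length. By limma on these ratios, 6606 genes had a higher and 129 a lower ratio in R172H than in KO (median difference 2.09), and 2360 a higher and 58 a lower ratio in add-back than in KO (median 0.92). The ratio of Api5, an inhibitor of apoptosis, was 7.32 ± 0.34 in R172H and 0.35 ± 0.62 in KO (difference 6.97, SE 0.58, adjusted p = 3.91e-11), and that of the proteasome gene Psmb6 differed by 6.56. Slc8a3, Mt1 and Ahi1 had 146, 47 and 143 promoter-proximal reads in R172H and 0, 0 and 1 in KO, so the size of their rise depends on the pseudocount. In Slc8a3, and in Gm38523 below, the sense density upstream was 9.84 and 13.9 times that of the body. Ratios were lower in R172H in Bola1 (−3.57), Lefty1 (−3.20), Gm38523 (−3.02) and Ripor3 (−6.61), which had 29.4%, 28.6%, 52.7% and 93.4% of their body reads in one 100-nt window. In add-back against KO the ratio of Rsbn1 was lower (−3.08) and that of Rps12 higher by 5.75, with 24.7% of its body reads in one window. The largest rises there, in Stap2, Taco1 and Hexb, had 78.2% to 98.4% of their body reads in one window. Other genes past the threshold had almost no reads to set a ratio in one group: Ophn1, Pax3 and Gm16580 had 1, 4 and 0 body reads in KO, Zfp503 had 1 promoter-proximal read in KO, and Mb21d2 had 0 promoter-proximal reads in add-back. The 18S ribosomal RNA sequence Rn18s-rs5 also passed it, and ribosomal reads differed by group as given above. With each library's ratios centred on its median, 1211 genes were higher and 2036 lower in R172H, and 249 higher and 388 lower in add-back. The median difference of add-back over KO was 0.7 over 6197 genes with matched reads, against 0.92 over 9504 genes with all reads. The count of 2418 in add-back over KO became 433 without add-back replicate 2, 662 without KO replicate 2 and 1449 without add-back replicate 1, and 110 of 6197 tested with matched reads, and its median became 0.58 without KO replicate 2 and 1.26 without KO replicate 1.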

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

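In the add-back libraries 33 antisense reads lay in the stretch of Trp53 that was depleted of sense reads in KO (chromosome 11, 69583001 to 69591000, mm10), against 0 in R172H and 0 in KO. The pseudogene Trp53-ps on chromosome 17 (54419597 to 54421236) had 287 reads in add-back, against 2 in R172H and 0 in KO. No score filter was applied to these counts, and scores ran down to 0 in add-back but only to 22 in R172H and KO. Reads with scores under 22 could therefore be counted in add-back alone, so the groups are not fully comparable here.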

How the results depend on the processing

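With matched reads 5101, 5444 and 4789 of 12453 genes were called in R172H over KO, add-back over KO and add-back over R172H, and 2269 were called alike in both comparisons with KO. Of the calls with all reads in genes tested in both, 62.5%, 69.3% and 66.8% were kept with matched reads and the same sign. Of those with matched reads, 88.1%, 94.8% and 90.7% were also made with all reads. A minimum 2-fold change left 2992, 2352 and 2274. Leaving out 1 library gave 6131 to 7719, 6102 to 8216 and 5274 to 7345 calls. With the replicate number as a replicate block the counts were 8073, 8276 and 7251; differences between replicates correlated between groups at 0.144, −0.07 and −0.025 over 10878 genes, so no pairing was used. Pausing counts became 3247 (R172H) and 637 (add-back) of 9504 with centred ratios and 4469 and 110 of the 6197 tested with matched reads (main 6735 and 2418 of 9504), and ran from 433 to 3511 in add-back when 1 library was left out. Element calls in R172H were 165 of the 194 tested with at least 50 reads per strand and 128 of the 157 beyond 20 kb from genes, and in add-back 117 and 109 of these. Of 758, 326 and 330 were called with factors from the elements (medians 0.01 and 0.02) and 230 and 166 with matched reads. Of the 2 elements near Cxcl1, 0 were called in R172H over KO with factors from the elements, 1 with matched reads, and 1 to 2 without 1 library (1 without R172H replicate 2). The nearer one had log2 changes of −0.12 and −1 in the first 2 settings. List shifts numbered 0, 0 and 0 of 23 by camera with an estimated correlation; fry, which tests a list against no change rather than against other genes, called 11, 12 and 15. Estimated correlations also gave 0 calls per comparison over 12 settings. At the preset correlation some lists changed. TGF-beta and YAP targets gained a call, down, in add-back over R172H with the neighbour offset (adjusted p = 0.00944), matched reads (0.00371), no piled windows (0.0306) and without R172H replicate 1 (0.024) or 2 (0.0249), and, up, in add-back over KO with matched reads (0.0091). Immediate-early genes gained one, down, in add-back over KO with the offset (0.0155) and without KO replicate 2 (0.00449), and, up, in R172H over KO with matched reads (0.0105, but 0.438 at an estimated correlation). Others that gained one, all down, were RAS-ERK output in add-back over KO (0.0435 without KO replicate 2) and, in add-back over R172H, NF-kB targets (0.0349 with the offset) and stress response (0.0341 with matched reads, 0.0317 without R172H replicate 2). Stress response lost its call in R172H over KO with matched reads (0.0521). Some single genes reversed or moved. Trp53 in add-back over R172H was −0.23 with matched reads and 0.01 to 0.26 without 1 library. In add-back over KO, Stap2 was 0.03 and Il1rapl1 2.14 without piled windows, Taco1 was 0.61 without them, 0.69 in the shorter body and 0.45 with matched reads, and Hbegf was 0.17 with the neighbour offset. Calls were lost for Dusp4 in add-back over R172H with that offset (−0.14) and for Samd9l in R172H over KO with matched reads (0.58). Calr in R172H over KO was −0.24 and Cxcl3 in add-back over R172H −0.11 with matched reads. A count-based test and a spike-in scaling were planned but not run, and the cause of these differences was not tested.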

Other observations

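Most of the other lists held genes that moved in either direction in R172H over KO. Of 32 p53 target genes, 9 were higher and 10 lower (10 and 10 when adjusted over the list alone; camera adjusted p = 0.915; adjusted p = 0.92 with an estimated correlation), with Ephx1 at log2 2.24 and Sesn2 at −2.35. NF-kB targets were higher in 11 and lower in 5 of 27 cases (11 and 5 over the list alone; adjusted p = 0.391; 0.676 with an estimated correlation), with Birc3 at 0.95 and Bcl2l1 at −0.75. Of 12 CC chemokine and colony-stimulating factor genes, 6 were higher, among them Csf1 and Cx3cl1, and 5 lower, among them Il34 (6 and 5 over the list alone; adjusted p = 0.915; 0.975 with an estimated correlation). Interferon-stimulated genes were higher in 7 and lower in 7 of 23 cases (7 and 8 over the list alone; adjusted p = 0.961; 0.975 with an estimated correlation), with Samd9l at 1.42, which was not called with matched reads (0.58, adjusted p = 0.295), and Ifi35 at −1.26. Sense reads 500 to 2500 nt upstream were denser than in the body of Il34 (5.1 times; it also overlaps a gene on its strand), Ifi35 (1.08 times) and Pfkfb4 (2.79 times), so the origin of their body reads is not settled. Hypoxia and glycolysis genes were higher in 15 and lower in 9 of 28 (adjusted p = 0.561; 0.823 with an estimated correlation), with Egln3 at 2.55 and Pfkfb4 at −2.69. Mesenchymal genes were higher in 12 and lower in 5 of 21 (adjusted p = 0.137; 0.515 with an estimated correlation), with Col1a1 at 3.9 and Zeb2 at −1.25. Immediate-early genes were higher in 11 and lower in 5 of 26 (12 and 5 over the list alone; adjusted p = 0.391; 0.891 with an estimated correlation), with Atf3 at −3.23; with matched reads the adjusted p was 0.0105, upward, at the preset correlation and 0.438 at an estimated one. RAS-ERK output genes were higher in 11 and lower in 7 of 23 (12 and 7 over the list alone; adjusted p = 0.724; 0.866 with an estimated correlation), with Spry1 at 2.11 and Dusp4 at −1.29.

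Ribosomal protein genes were higher in 7 and lower in 16 of 46 (adjusted p = 0.183; 0.866 with an estimated correlation). DNA replication genes were higher in 11 and lower in 4 of 36 (10 and 4 over the list alone; adjusted p = 0.812; 0.877 with an estimated correlation), with Rrm2 at 1.17. Antigen presentation genes were higher in 2 and lower in 2 of 11 (adjusted p = 0.873; 0.891 with an estimated correlation), and basal genes higher in 4 and lower in 3 of 11 (adjusted p = 0.969; 0.975 with an estimated correlation), with a median of −0.01 and a mean of 0.14. Cell-type markers with few tested genes were fibroblast (2 higher of 4, median 0.73, or 0.79 with bounds), endothelial (1 higher and 2 lower of 5), acinar and islet (1 higher and 2 lower of 7) and immune (0 called of 5) genes. Camera gave adjusted p = 0.561, 0.993, 0.647 and 0.792 for them (0.866, 0.993, 0.866 and 0.877 with an estimated correlation). The endothelial gene Emcn, at least 114.7-fold higher, had 97.1% of its reads in one 100-nt window.

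The tests of chromosome-wide shifts were chosen after the shifts were seen. Copy number differing between the lines is a candidate explanation, and reads more than 20 kb from genes should then follow the gene medians over 20 chromosomes. The lowest Spearman correlation of the 3 comparisons was 0.31 (R172H over KO, permutation p = 0.2), against 0.62 (adjusted permutation p = 0.006) and 0.66 (adjusted permutation p = 0.006) in add-back over KO and over R172H, which leaves it open. In add-back over R172H, reads far from genes moved with the gene medians on chromosomes 12 (−0.60), 1 (0.29) and 17 (0.79). On chromosome 8, which had the largest shift, they went the other way (0.13 against −0.61). Differences in read length, score and duplicates were argued against, since at least 94.5% of the spread of the medians was kept with matched reads.

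The tests of the promoter-proximal excess in R172H were chosen after it was seen, and the prediction for mutant p53 was written after the result. Score and duplicates as its source were argued against, as 83.2% of the median difference was kept with matched reads (2.36 to 1.96 over 6197 genes). For read length this test cannot decide. Reads of 30 to 50 nt are longer than the medians of R172H (25 and 24 nt) and shorter than those of KO (52 and 60 nt). Were it due to mutant p53, add-back should show it too; its median difference over KO was 44% of that of R172H. That difference ran from 0.58 without KO replicate 2 to 1.26 without KO replicate 1, which leaves mutant p53, preparation and other differences between the lines open.

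The tests of Y-linked genes were chosen after their reads were seen, and the prediction on loss of the chromosome was written after the result. Kdm5d, Eif2s3y and Uty had 24, 36 and 70 reads in R172H, 0, 0 and 1 in KO and 2, 0 and 0 in add-back. Short or repeated reads assigned to the Y were argued against, as the share kept with matched reads was 96.6% of that of all genes. Loss of the whole Y in KO stays open. Its test rested on Gm33272, at 59.6% of the R172H level in KO, but this gene lies in the part of the Y that pairs with the X (90793687 to 90806846), and reads from the X copy could give such a level.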
